A study of Mus musculus with 16 samples.

How the data were processed

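RNA from inguinal and epididymal white fat of singly housed obese male mice was hybridised to 16 bead arrays, 4 for each combination of depot and diet. Per the labels, the mice were 17 weeks old when the experimental diets began and 21 weeks old at the end, RNA was taken up in TriReagent and cleaned on columns with DNase, its quality was checked on a Bioanalyzer, and 400 ng were amplified to biotin-labelled RNA. The submitters' processing notes name GenomeStudio and limma 3.18.13, and the role of either tool is not given in the sources used here.

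Per the file headers, the deposited scanner table holds an average signal intensity and a detection p-value for each of 25697 probes on each array. The values are linear, not background-subtracted, and at least 92.2. The deposited detection p-value compares a probe with the array's negative control beads in steps of about 0.00125. The authors also deposited normalized signal intensities, whose values show a subtracted background (25% are at or below 0) and equal quantiles on all arrays; the exact steps are not given in the sources used here. Within each array the normalized and scanner values had a rank correlation of at least 0.999997, and the series value table held the same normalized values (largest difference 0). Its scale is linear and its genes are not centred. No pair of arrays had identical values (0 pairs), and 0 columns of values were left unmapped.

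The analysis started from the scanner intensities. The background was corrected with neqc in limma 3.58.1 (R 4.3.3), a normal-exponential fit guided by the detection p-values, with an offset of 16, quantile normalization and log2. Probes with a detection p under 0.05 on at least 4 of the 16 arrays were kept (15052 probes). Names came from the arrays' own gene names, updated through NCBI RefSeq gene tables of assembly GRCm38.p6, which served for names only, since the build behind the arrays is not given in the sources used here. By current symbol 20736 probes matched, 3872 matched through a synonym of 1 gene, 104 had a synonym of several genes and 985 had no match, and the last 2 kinds kept the array's name. Array names differed between the tables for 32 probes. For each of the 11050 genes left the kept probe with the highest mean was tested, and the text says where other probes of a named gene of interest differed in sign.

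Each comparison used limma's lmFit and eBayes with 4 group means over all 16 arrays, so that the groups shared 1 estimate of the spread. The contrasts were scoparia minus control in iWAT and in eWAT, the difference of these, and iWAT minus eWAT in each diet. The effect over both depots was tested on the mean of both depots per animal (8 means). P values were adjusted by Benjamini-Hochberg over all genes of a contrast, and adjusted p under 0.05 was the threshold, with no minimum fold. A gene detected on no array of 1 group has only a bound there, given as "at least N-fold": the brighter group's mean log2 value against the dim group's mean of, per array, the higher of the dim probe's value and the lowest value among detected probes. The labels do not say how RNA samples relate to tissue pieces, so p values measure the spread between these mice and pieces together.

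There were 22 pathway lists and 10 cell type lists, all tested with camera at a preset correlation of 0.01 if at least 5 members were measured (32 of 32). The camera test with an estimated correlation and fry, which asks whether a list's genes move on balance 1 way, were alternatives. Named genes followed a rule. They were, for each diet contrast and the depot contrast in control mice, the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap. Genes with predicted names were counted only. Where fewer than 12 passed, they were filled up to 8 in a direction by p and given as values. To these came up to 4 members of each list by p and 32 adipose genes of interest, of which 28 were tested. Acaca matched no probe name, Ucp1 and Il6 were detected on 3 arrays and Cyp1a1 on 0, so these were not tested. Up to 6 genes in each direction were named for the difference between depots.

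The animal numbers in the labels (1 to 4 and 16, 17, 18, 20) are alike in both depots, so that the depots were taken as paired by animal; the labels give the numbers, not a statement of pairing. Deviations from the group means of an animal's iWAT and eWAT arrays correlated at 0.315, -0.207, 0.201 and 0.00258 in control mice and 0.25, 0.034, 0.249 and 0.0676 in scoparia mice, with a consensus correlation of 0.0615. With the animal as a block, 405 genes passed for depot in control mice and 1887 for depot in scoparia mice. Both of these fits used only the 8 arrays of their diet and a spread estimated from them. Their counts therefore do not show the effect of the pairing alone. For the difference between depots, fitted with the block on all 16 arrays, 0 genes passed.

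Before the real contrasts, the fits were tested on simulated arrays with 100 genes shifted by a log2 change of 1 and 100 shifted by 2 among 11050. The mean and spread of each gene came from the real arrays, with noise alike in all groups and independent between genes. The simulation held no deviating arrays and no difference in spread between depots. Its shares therefore cannot tell the power in iWAT from that in eWAT. The share recovered at a change of 1 was 62% in iWAT, 52% in eWAT, 80% over both depots, 24% for the difference, 55% for depot in control and 57% for depot in scoparia mice, and at a change of 2 it was 97%, 93%, 99%, 81%, 95% and 97%. Alternatives were the authors' normalized values (log2 of the value, set to 0 if negative, plus 16), no background correction, median scaling, an offset of 50, no detection filter, detection p under 0.01 on at least 8 arrays, all detected probes, eBayes with trend and robust fits, array weights, an adjusted p of 0.10, each depot's 8 arrays alone, blocks, and each array or animal left out in turn. Added after the data were seen were fits without iWAT control arrays 1 and 4, without eWAT control array 2 and without other pairs of iWAT arrays, covariates for marker means and for the share of probes detected, and, for the depot lists, fry, the animal as a block and single arrays left out. Chip, slide and scan date are not given in the sources used here, so the planned block on the chip was not run and a batch can be neither tested nor excluded. Exact tests counted all splits of the samples, 35 for 8 arrays into 4 and 4, or 70 ordered ones. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.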

Results

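Gene expression was measured on 16 Illumina bead arrays of white adipose tissue from diet-induced obese male C57BL/6J mice. Inguinal fat (iWAT), a subcutaneous depot, and epididymal fat (eWAT), a visceral depot, were each sampled. The mice had fed for 4 weeks on a diet with 60% of its energy as fat, either alone (control) or with 1% by weight of an extract of the plant Artemisia scoparia (scoparia). Each of the 4 groups held 4 arrays, and the animal numbers in the labels were alike in both depots, so that 8 mice gave 1 array per depot. Between 50.5% and 56.2% of the 25697 probes were detected per array, the median probe signal ran from 128 to 175. The number of arrays limited the precision, and 11050 genes were tested. Log2 changes are given ± SE, which uses the spread shared by all groups of a fit. Group means are given ± SD, with n = 4 arrays per group.

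The first principal component carried 40.6% of the variance and the second 24.5%. On the first, 7 of the 8 eWAT arrays lay between 23.4 and 44.9, eWAT control array 2 lay at -9.32, and all iWAT arrays lay below it. On the second, iWAT control arrays 1 and 4 lay at 48.7 and 34.2, whereas the other 6 iWAT arrays lay between -59.9 and -13.8. In iWAT the share of probes detected was 50.5%, 51.7%, 52.1% and 51.3% on the control arrays and 52.7%, 55.0%, 55.2% and 56.2% on the scoparia arrays, a difference of 3.38 percentage points (exact two-sided permutation p = 0.0286, n = 4 per group).

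**Figure D1:**
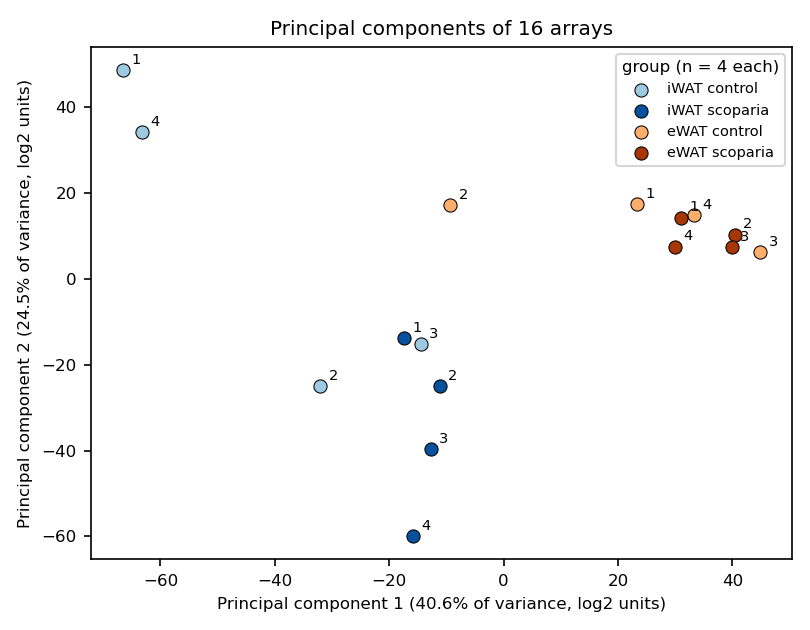
Scores of the 16 arrays on the first (40.6% of the variance) and second (24.5%) principal components of the log2 values of 11050 genes, 1 point per array, coloured by depot and diet. On the second component, iWAT control arrays 1 (48.7) and 4 (34.2) lie apart from the other iWAT arrays, and eWAT control array 2 lies at -9.32 on the first.

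In inguinal fat, the question was which genes the extract altered in obese mice. Of 11050 genes, 972 passed an adjusted p of 0.05, with 487 higher and 485 lower in scoparia mice and 407 changed at least 2-fold. The SE and p values rest on the spread shared by all 4 groups, and with the 8 iWAT arrays alone no gene passed. Mean correlations of an array with its own group were 0.938 to 0.952 in iWAT control and 0.988 to 0.990 in eWAT scoparia mice. They were 0.958 to 0.981 in iWAT scoparia and 0.955 to 0.979 in eWAT control mice. The shared spread may therefore understate that in iWAT. Among the called genes whose groups did not overlap, coagulation factor VIII (F8) rose most, from 6.08 ± 1.05 to 8.52 ± 1.05 on the log2 scale, by 2.45 ± 0.49 (5.46-fold, adjusted p = 0.019). Ddx3y, a Y-linked RNA helicase, rose by 2.21 ± 0.44 and Chka, choline kinase alpha of phosphatidylcholine synthesis, by 2.20 ± 0.44 (both adjusted p = 0.019). Siglech, a receptor of plasmacytoid dendritic cells, rose by 2.27 ± 0.59 (adjusted p = 0.0328) and Gimap8, a GTPase of the immunity-associated family, by 2.24 ± 0.48 (adjusted p = 0.0211). Tapbp, the tapasin chaperone that loads peptides onto MHC class I, fell most, from 9.66 ± 1.08 to 7.44 ± 0.50, which is -2.22 ± 0.40 (adjusted p = 0.0182). A pair of sulfur-metabolizing enzymes, Tst (thiosulfate sulfurtransferase) and Cbs (cystathionine beta-synthase), fell by 1.51 ± 0.22 (adjusted p = 0.0172) and 1.57 ± 0.32 (adjusted p = 0.019). The homeobox factor Gsc fell by 1.37 ± 0.22, the CTCF paralog Ctcfl by 1.97 ± 0.37 and the Fc receptor-like scavenger receptor Fcrls by 1.26 ± 0.24 (each adjusted p = 0.0182).

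The other genes that the naming rule gave in iWAT rose or fell by a similar amount. BC030476 (2.42), the peptide transporter Slc15a2 (2.19), the histone H2A deubiquitinase Mysm1 (2.09), the rhomboid protease Rhbdl2 (2.07), the small nuclear RNA transcription factor subunit Snapc3 (2.06), the zinc finger gene Zfp292 (2.02) and Rev3l, the catalytic subunit of DNA polymerase zeta (1.99), rose with adjusted p from 0.0182 to 0.0262. Gipc1 (-1.78), proteinase 3 of neutrophil granules (Prtn3, -1.59), Hps5 (-1.51), the vacuolar proton pump subunit Atp6v0e2 (-1.34), annexin Anxa8 (-1.30) and the anti-Müllerian hormone receptor Amhr2 (-1.30) fell with adjusted p from 0.0183 to 0.0312. The naming rule took these 24 from the 699 of the 972 genes for which all 4 scoparia arrays lay on 1 side of all 4 control arrays. Slc15a2 was detected on 1 of the 4 control arrays, Siglech on 2, and F8, Mysm1 and Rev3l on 3. Cbs was detected on 1 of the 4 scoparia arrays and Prtn3 on 2. Of these 24 genes only Gsc passed in the test of the difference between the depots given below, and none did with the animal as a block.

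**Figure D2:**
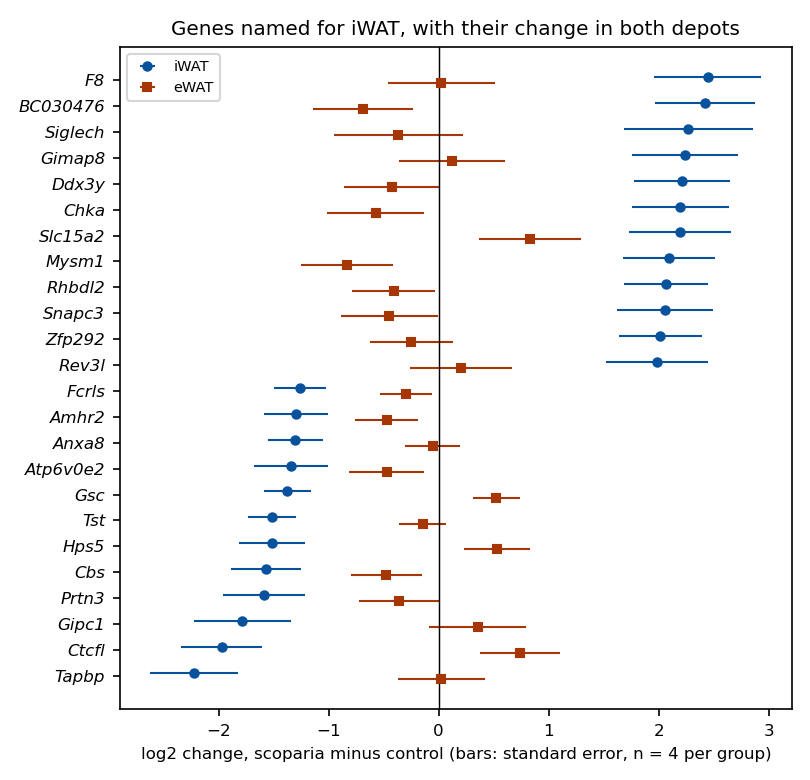
Log2 change (scoparia minus control) ± SE of 24 named genes in iWAT and in eWAT, 4 arrays per group. The 24 were named for passing the threshold in iWAT, where F8 stands at 2.45. Only Gsc passed in the test of the difference between the depots, and none did with the animal as a block.

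Of the 32 gene lists, which were chosen before the data were examined, as were the tests, the naming rule and most other settings, 3 passed camera's test in iWAT. B cell markers were higher, with 9 of 9 measured members positive and a median of 1.88 (adjusted p = 0.00284). Over all genes 0 of these members passed, and 8 passed when adjusted over the list alone, among them the tyrosine kinase Blk at 2.17 ± 0.73, detected on 3 of the 4 control arrays. T and NK cell markers were higher, with 9 of 9 members positive and a median of 1.20 (adjusted p = 0.0159), and perforin (Prf1) rose by 1.59 ± 0.34 (adjusted p = 0.0209), while Cd8b1 stood at 1.65 ± 0.77 (adjusted p = 0.148). Oxidative phosphorylation, the subunits of the respiratory chain and ATP synthase, was lower, with 3 of 22 members positive and a median of -0.28 (adjusted p = 0.0382). Its members passed neither over all genes (0) nor adjusted over the list alone (0), and succinate dehydrogenase subunit Sdhb stood at -0.61 ± 0.20 (adjusted p = 0.0587). With an estimated correlation the adjusted p = 0.958 for each of these 3 lists. On the arrays, the mean of the B cell markers was 0.36 ± 1.26 in control and 2.05 ± 1.34 in scoparia mice, a difference of 1.69 (exact two-sided permutation p = 0.171, n = 4 per group). That of the T and NK cell markers differed by 1.13 (exact p = 0.229).

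In 9 further lists that did not pass as a whole, single members did. The lactate and niacin receptors of adipocytes, Hcar1 and Hcar2, which restrain lipolysis, fell by 1.23 ± 0.29 (adjusted p = 0.0262) and by 1.00 ± 0.25 (adjusted p = 0.0319). They are 2 of the 18 measured lipolysis genes (list adjusted p = 0.492; adjusted over the list alone, 1 higher and 3 lower). DNA topoisomerase Top2a rose by 1.71 ± 0.27 (adjusted p = 0.0182) and ribonucleotide reductase Rrm2 by 0.80 ± 0.19 (adjusted p = 0.0278) among 16 proliferation genes, of which 14 were positive (list adjusted p = 0.0671; 2 adjusted over the list alone). Rrm2 was detected on 2 of the 4 control arrays. Cyp1b1, a target of the aryl hydrocarbon receptor, rose by 1.54 ± 0.42 (adjusted p = 0.0381). The exporter Abcc3 fell by 0.74 ± 0.22 (adjusted p = 0.0499), and both belong to 19 xenobiotic and antioxidant genes (list adjusted p = 0.492; 2 higher and 1 lower adjusted over the list alone). Of 12 interferon response genes, Ifit2 rose by 1.08 ± 0.29 (adjusted p = 0.0345). Mx1, which was detected on 3 scoparia arrays and not on any control array, was at least 1.12-fold higher (adjusted p = 0.031; list adjusted p = 0.492; 2 higher and 1 lower adjusted over the list alone). The adhesion molecule Vcam1 rose by 1.38 ± 0.40 (adjusted p = 0.0443; inflammatory list, adjusted p = 0.514; 2 adjusted over the list alone). Klf6 rose by 1.17 ± 0.24 (adjusted p = 0.019; immediate early list, 0.795; 1) and Cd55 by 0.70 ± 0.21 (adjusted p = 0.0494; progenitor list, 0.492; 1). The limb patterning factor En1 fell by 1.01 ± 0.19 (adjusted p = 0.0182) among 6 genes known to be higher in subcutaneous fat (list adjusted p = 0.138; 4 lower adjusted over the list alone). The phosphatase Acp5 fell by 0.85 ± 0.21 (adjusted p = 0.03) among 14 markers of lipid-associated macrophages (list adjusted p = 0.795; 1). Over 32 settings Cd55 and Abcc3 stayed called in 11, Vcam1 in 14 and Cyp1b1 in 15. The changes of Cd55 and Abcc3 shrank to as little as 0.07 and -0.26. The other members named in this paragraph stayed called in 19 to 25 of 31 or 32 settings.

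The remaining 20 lists had no member past the threshold over all genes, and their adjusted p ran from 0.371 for erythroid markers to 0.961 for mesothelial markers. They were de novo lipogenesis (0.492), triglyceride synthesis (0.492), adipocyte identity (0.492), adipokines (0.795), insulin signalling (0.89), thermogenic adipocyte genes (0.492) and fatty acid oxidation (0.492). Further ones were the tricarboxylic acid cycle (0.492), branched-chain amino acid catabolism (0.492), cholesterol synthesis (0.828), extracellular matrix (0.492), the unfolded protein response (0.492), the circadian clock (0.492), and genes higher in visceral fat (0.795). The last were markers of macrophages (0.795), endothelium (0.621), mesothelium, skeletal muscle (0.828), epithelium (0.492) and red cells. Adjusted over the list alone, 1 gene was higher and 3 were lower in each of de novo lipogenesis and branched-chain amino acid catabolism, 1 was higher and 1 lower among adipokines, and 1 was lower among erythroid markers. The median, mean and test differed in sign for adipokines, the inflammatory list, genes higher in visceral fat and mesothelial markers.

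None of the 28 measured adipose genes of interest passed in iWAT. The largest values were those of the beta-3 adrenergic receptor Adrb3 (-1.50 ± 0.49, adjusted p = 0.0588), fatty acid synthase Fasn (-1.14 ± 0.41, 0.0733), and Cebpa (-1.06 ± 0.33, 0.0524). Then came Saa3 (-1.03 ± 0.63), Trem2 (-0.99 ± 0.54), hormone-sensitive lipase Lipe (-0.96 ± 0.45) and the insulin-responsive glucose transporter Slc2a4 (-0.90 ± 0.41, 0.141). Srebf1 stood at -0.76, Pck1 at -0.77, Plin1 at -0.71, Pnpla2 at -0.46, Lcn2 at -0.30, Adgre1 at -0.28 and Nqo1 at -0.26. Adiponectin (Adipoq, 0.02 ± 0.16), leptin (0.18), Pparg (0.21, with 2 other probes of opposite sign), Irs1 (0.12, detected on 1 of the 4 control arrays) and Insr (-0.09) lay close to 0. So did Acly (0.13), Scd1 (0.11), Dgat2 (-0.03), Ppargc1a (-0.06), Ccl2 (0.15), Tnf (0.10), Cd68 (-0.04) and Itgax (-0.07). When arrays were scaled to equal medians instead of equal quantiles, Adipoq turned to -0.82 (adjusted p = 0.0173), and leptin, Pparg, Acly, Scd1 and Ppargc1a also changed sign without passing.

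The iWAT count rested on single arrays: without iWAT control arrays 1, 2, 3 and 4 in turn it was 5, 2051, 3050 and 0, and without iWAT scoparia arrays 2, 3 and 4 it was 201, 0 and 243. Without eWAT control arrays 1 and 2 it was 602 and 1524, and without eWAT scoparia arrays 1 to 4 it was 590, 566, 556 and 643. Without both iWAT control arrays 1 and 4, an alternative chosen after the data were seen, 4 genes passed, 3 of them among the 972. Other settings moved it too: median scaling gave 2960 genes (595 higher, 2365 lower, with the median of all genes at -0.231 instead of -0.0572). Array weights gave 2154 and the 8 iWAT arrays alone gave 0. With the B cell marker mean or the share of probes detected as a covariate it was 2 and 0. Both covariates were higher in iWAT scoparia mice, the share without overlap. These fits therefore cannot part the covariates from the diet. The 3 lists became 0 without iWAT control array 3, 5 without iWAT scoparia array 1 and 1 without iWAT scoparia array 4.

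**Figure D3:**
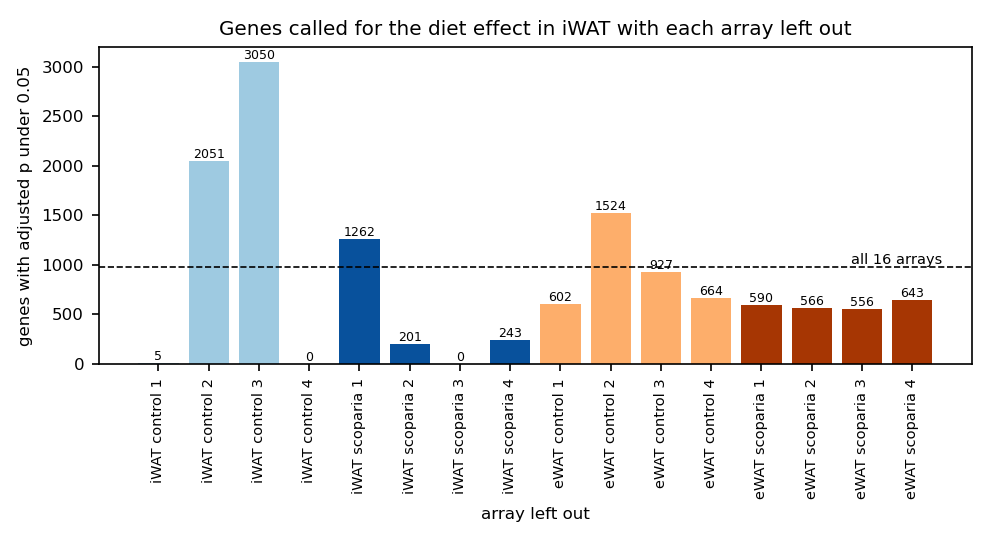
Number of genes past the threshold for the diet effect in iWAT when each of the 16 arrays is left out in turn (bars, from 0), with the count over all 16 arrays (972) as a dashed line. The count runs from 0 without iWAT control array 4 or iWAT scoparia array 3 to 3050 without iWAT control array 3.

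In epididymal fat no single gene passed (limma, 0 of 11050; 654 at an unadjusted p under 0.05; smallest adjusted p = 0.22), but 6 gene lists passed camera's test, with adipocyte genes lower and markers of lipid-associated macrophages and of mesothelium higher in scoparia mice. With an estimated correlation none of the 6 passed (adjusted p = 0.98, and 0.985 for triglyceride synthesis), and without eWAT control array 2 there was 1 list and the difference of the adipocyte identity score went from -0.272 to -0.029. Adipocyte identity genes were lower, with 6 of 21 positive (adjusted p = 0.0267; 1 lower adjusted over the list alone). Insulin signalling genes were lower, with 5 of 15 positive (adjusted p = 0.0344; 2 lower adjusted over the list alone), and the insulin receptor substrate Irs2 stood at -1.26 ± 0.40. Triglyceride synthesis genes, with 2 of 18 positive, and lipolysis genes, with 4 of 18 positive, were also lower (both adjusted p = 0.0344; 0 adjusted over either list alone). The acyltransferase Gpam stood at -0.60 ± 0.24, Adrb3 at -1.12 ± 0.49 and Lipe at -0.88 ± 0.45 (its other probe of opposite sign). Markers of lipid-associated macrophages were higher, with 12 of 14 positive and a median of 0.55 (adjusted p = 0.0243; 0 adjusted over the list alone), and the receptors Clec7a and Trem2 stood at 0.79 ± 0.43 and 0.77 ± 0.54. Mesothelial markers were higher, with 8 of 9 positive (adjusted p = 0.0243; 3 higher adjusted over the list alone, namely Upk1b at 0.75 ± 0.22, Gpm6a at 1.09 ± 0.38 and Krt18 at 0.68 ± 0.26, the last detected on 3 of 4 arrays in each diet).

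The other 26 lists in eWAT had adjusted p from 0.125 for de novo lipogenesis to 0.971 for the extracellular matrix. The median, mean and test differed in sign for fatty acid oxidation, the extracellular matrix, B cell markers and muscle markers. Among the genes with the smallest p, given as values only, were Fam107a (0.99 ± 0.19), Slc38a5 (0.77), Vat1l (0.98) and Smyd4 (0.78) on the positive side. Ms4a2 was at least 1.51-fold, Wee1 at least 1.32-fold and Ptk7 at least 1.57-fold higher than control arrays on which they were not detected. On the negative side stood the endoplasmic reticulum chaperone Pdia4 (-1.49 ± 0.28), the RNA helicase Ddx6 (-1.20 ± 0.23), Zc3h13 (-1.65 ± 0.32), Reep3 (-1.25), Eif4b (-1.17), Bach1 (-1.20), Man2a2 (-1.20) and Pdpk1 (-1.18). All of these had adjusted p between 0.22 and 0.293. Of these, Fam107a was detected on 3 of the 4 control arrays, Bach1 on 3 and Man2a2 on 2 of the 4 scoparia arrays.

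Among the adipose genes of interest in eWAT, Fasn stood at -0.75, Slc2a4 at -0.59, Cebpa at -0.48, Plin1 at -0.45, Ppargc1a at -0.32, Adgre1 at 0.60, Lcn2 at 0.29, Ccl2 at -0.27 and Tnf at -0.24. The others, Adipoq (-0.09), leptin (0.23), Pparg (0.18), Irs1 (0.02), Insr (0.01), Acly (-0.14), Scd1 (0.04), Srebf1 (-0.05), Pck1 (-0.15), Dgat2 (-0.13), Pnpla2 (-0.23), Saa3 (-0.12), Cd68 (0.15), Itgax (0.16) and Nqo1 (-0.02), lay closer to 0. Adipoq, Acly, Srebf1, Dgat2 and Saa3 changed sign with median scaling. For Pparg and Adgre1, 1 of 2 other probes had the opposite sign. The gene count was 3 without eWAT control array 3, 14 without eWAT scoparia array 1 and 147 with array weights. The list count was 1 without eWAT control array 2, 11 without eWAT control array 3, 0 without eWAT scoparia array 2 and 1 without eWAT scoparia array 3.

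Over both depots, with 1 mean per animal, no single gene passed either (limma, 0 of 11050; 2390 at an unadjusted p under 0.05; smallest adjusted p = 0.157), while 5 gene lists did. Proliferation genes were higher, with 15 of 16 positive (adjusted p = 0.0203; 4 higher adjusted over the list alone), including Top2a at 0.92 ± 0.18 and the replication helicase subunits Mcm6 and Mcm4 at 0.59 ± 0.17 and 0.59 ± 0.19. B cell markers (adjusted p = 0.0203) and T and NK cell markers (adjusted p = 0.0428) were higher, with 9 of 9 members positive in each and 0 adjusted over either list alone. In eWAT alone 5 of 9 B cell markers (median 0.02, adjusted p = 0.862) and 3 of 9 T and NK cell markers (median -0.08, adjusted p = 0.747) were positive. Adipocyte identity genes (adjusted p = 0.0491; 6 of 21 positive) and oxidative phosphorylation genes (adjusted p = 0.0428; 5 of 22 positive) were lower, with 0 adjusted over either list alone, Cebpa at -0.77 ± 0.21 and Lipe at -0.92 ± 0.27. The proliferation score of eWAT control array 2 was -0.67 against 0.33 to 0.39 on the other 3 eWAT control arrays, and without control mouse 2 neither proliferation (adjusted p = 0.247) nor adipocyte identity (adjusted p = 0.268) passed. With an estimated correlation the adjusted p = 0.975 for all 5, and the other 27 lists had adjusted p from 0.0703 to 0.954. The median, mean and test differed in sign for adipokines, immediate early genes and endothelial markers.

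The genes with the smallest p over both depots, all with adjusted p = 0.157, were on the positive side the mitotic kinesin Kif15 (0.83 ± 0.13), the adhesion molecule Cxadr (1.30 ± 0.20), Lrch1 (0.89), Mns1 (1.17), the thrombin receptor F2r (0.86), Dbf4 (0.82), the kinetochore gene Cenpq (0.94) and Rab27a (0.86). On the negative side were Snx21 (-0.81 ± 0.12), the matrix metalloproteinase Mmp9 (-0.91 ± 0.14), Tmco6 (-0.72), Hsd17b11 (-0.63), Pld2 (-0.74), Tst (-0.83), the macrophage growth factor Il34 (-0.60) and Eif4b (-0.83). Kif15, Cxadr and Mns1 were detected on 2 of the 4 iWAT control arrays. Of the adipose genes of interest, Adrb3 stood at -1.31 ± 0.36 (adjusted p = 0.159), Fasn at -0.95 (0.17), Slc2a4 at -0.75 (0.17), Plin1 at -0.58, Saa3 at -0.58, Pck1 at -0.46 and Srebf1 at -0.41. Cebpa and Lipe are given above, and the 18 others lay between -0.35 for Pnpla2 and 0.21 for leptin. Of these, leptin, Pparg, Scd1, Lcn2 and Cd68 changed sign under median scaling. The gene count became 2101 without control mouse 3 and 2796 with array weights. The list count became 1, 3, 3 and 3 without control mice 1 to 4, and 8, 3, 0 and 0 without scoparia mice 16, 17, 18 and 20.

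Without a block on the animal, the effect of the extract differed between the depots for 6 genes (1793 at an unadjusted p under 0.05). Of these, 5 had a higher and 1 a lower change in iWAT than in eWAT. With the animal as a block no gene passed. The deubiquitinase Mindy2 differed by 2.23 ± 0.37 (adjusted p = 0.0407), with 1.30 in iWAT and -0.94 in eWAT. Reep3, a shaper of the endoplasmic reticulum, differed by 2.07 ± 0.35 (adjusted p = 0.0407), and the HMG box factor Bbx by 2.01 ± 0.30 (adjusted p = 0.0273). The RNA-binding protein Larp4b differed by 1.94 ± 0.33 (adjusted p = 0.0407; detected on 2 of the 4 iWAT control arrays). A gene with a predicted name differed by 1.58 ± 0.20 (adjusted p = 0.00789). Gsc differed by -1.90 ± 0.30 (adjusted p = 0.0407), with -1.37 in iWAT and 0.52 in eWAT, where it was detected on 3 of the 4 control arrays. Klf7 (1.47), Clcn3 (1.42), Vat1l (-1.64), Ctcfl (-2.71), Clec16a (-0.88), Naprt (-1.12) and Hps5 (-2.04) came next, with adjusted p from 0.0581 to 0.0688.

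Among the lists, the difference between depots was positive for B cell markers (adjusted p = 0.00335; 9 of 9 positive) and T and NK cell markers (adjusted p = 0.0145; 9 of 9 positive; 1 adjusted over the list alone). It was negative for genes known to be higher in subcutaneous fat (adjusted p = 0.0249; 1 of 6 positive; 2 adjusted over the list alone). With an estimated correlation the adjusted p = 0.974 for each, and the other 29 lists ran from 0.245 to 0.947. The median, mean and test differed in sign for de novo lipogenesis, triglyceride synthesis, lipolysis, adipocyte identity, adipokines, insulin signalling, cholesterol synthesis and the circadian clock. Across genes, which are not independent replicates, the changes in the 2 depots correlated at r = 0.191 (rho = 0.227), and 12 of 35 splits of the 8 mice gave as high a value (exact one-sided p = 0.343). Of the 972 genes called in iWAT, 553 (56.9%) had the same sign in eWAT.

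With the animal as a block, the paired fit gave 0 genes for the difference, and median scaling gave 529 (85 higher, 444 lower; median of all genes -0.338). The count was 428 without iWAT control array 3, 18 without eWAT control array 3, 39 without eWAT scoparia array 1 and 1 without any other single array except eWAT control array 4, where it was 7. Array weights gave 626 genes, and without iWAT control arrays 1 and 4 there was 1. The 3 lists became 0 without iWAT control array 3, 1 without iWAT scoparia array 4 and 5 without eWAT control array 2.

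The depots of control mice differed at 2743 genes, 1446 higher in iWAT and 1297 higher in eWAT, 1107 of them at least 2-fold. The subcutaneous homeobox gene Hoxc10 was at least 15.6-fold higher in iWAT (adjusted p = 8.6e-09), with log2 values of 7.43 to 9.11 on the 8 iWAT arrays and 4.40 to 4.71 on the 8 eWAT arrays, where it was not detected. The mesothelial uroplakins Upk3b and Upk1b were at least 25.9-fold (adjusted p = 2.59e-10) and 16.8-fold (adjusted p = 1.06e-09) higher in eWAT. The immediate early factor Fosb (4.42 ± 0.42) and Cidea, a lipid droplet protein of thermogenic adipocytes (3.26 ± 0.38, 9.57-fold), were higher in iWAT (adjusted p = 1.18e-05 and 6.86e-05). Osteopontin (Spp1, -4.03 ± 0.71, adjusted p = 0.00164), the metalloelastase Mmp12 (-3.16 ± 0.51, adjusted p = 0.000853) and the endosomal receptors Tlr13 (-3.49) and Tlr8 (-3.42) were higher in eWAT.

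Also higher in iWAT were the major urinary proteins Mup6 (3.70) and Mup1 (3.66), whose near-identical paralogs make the gene uncertain, the muscle troponin Tnnc2 (3.47 ± 1.15), Adh7 (3.46), Vat1l (3.05), Cyp2f2 (2.98) and Osr2 (2.88). Glycam1, a mucin of lymph node venules, was at least 8.21-fold higher and was detected on 3 of the 4 iWAT control arrays. Also higher in eWAT were Slpi (-3.79), the similar receptors Lilr4b (-3.58) and Lilrb4a (-3.21), Tnfrsf11b (at least 7.44-fold), the prostaglandin D synthase Hpgds (-3.41) and Cd84 (-3.20). The naming rule took these genes from those whose iWAT and eWAT control arrays did not overlap, and their adjusted p was at most 0.0397. Adh7 was detected on 1, Cyp2f2 and Tnnc2 on 2 and Mup6 on 3 of the 4 eWAT control arrays, and Hpgds on 1, Tlr8 on 2 and Spp1 on 3 of the 4 iWAT control arrays.

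Of the lists, 14 passed camera's test in control mice, 10 higher in iWAT and 4 higher in eWAT. Over all genes, 0 genes of oxidative metabolism passed as lower in iWAT. Those that passed as higher were 10 of 22 oxidative phosphorylation genes (adjusted p = 5.08e-05), 9 of 20 fatty acid oxidation genes (0.00416) and 6 of 17 genes of the tricarboxylic acid cycle (0.00516). Higher in iWAT as well were 7 of 17 genes of branched-chain amino acid catabolism (0.0227) and 6 of 10 thermogenic genes (0.000647), among them Cox8b (2.09 ± 0.31) and Acat1 (1.34 ± 0.23). Genes known to be higher in subcutaneous fat were higher in 5 of 6 cases (adjusted p = 1.7e-06), with Hoxc9 at 2.07 ± 0.21, as were 5 of 18 lipolysis genes (0.0384), with Hcar2 at 1.63 ± 0.25 and Hcar1 at 1.44 ± 0.29. Markers of muscle (3 of 12; 0.00283), endothelium (4 of 12; 0.00946) and B cells (1 of 9; 0.0289), with Cd79b at 3.13 ± 0.78, were also higher in iWAT. On iWAT control arrays 1 to 4 the muscle scores were -0.92, 1.90, 4.31 and -0.34, beside -1.53 to -0.82 in eWAT control mice. The B cell scores were -1.15, 1.94, 0.40 and 0.26, beside -1.61 to -0.51. Array 1 thus lay within the eWAT range for both. Macrophage markers were higher in eWAT in 15 of 19 cases (adjusted p = 2.56e-09), with Cd68 at -2.37 ± 0.35, and markers of lipid-associated macrophages in 12 of 14, with 1 lower (2.06e-07). Mesothelial markers were higher in eWAT in 7 of 9 cases, with 1 lower (1.42e-08), and proliferation genes in 3 of 16 (0.00939), with Top2a at -1.49 ± 0.27. Adjusted over the list alone, the counts in the list's direction were 15, 11, 12, 7, 6, 5, 6, 9, 4, 4, 17, 12, 7 and 2 in the order given. In the opposite direction 1 member passed in each of fatty acid oxidation, the tricarboxylic acid cycle, lipolysis, lipid-associated macrophages and mesothelium. With an estimated correlation the adjusted p ran from 0.148 to 0.62 for these 14 lists and 0 passed.

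**Figure D4:**
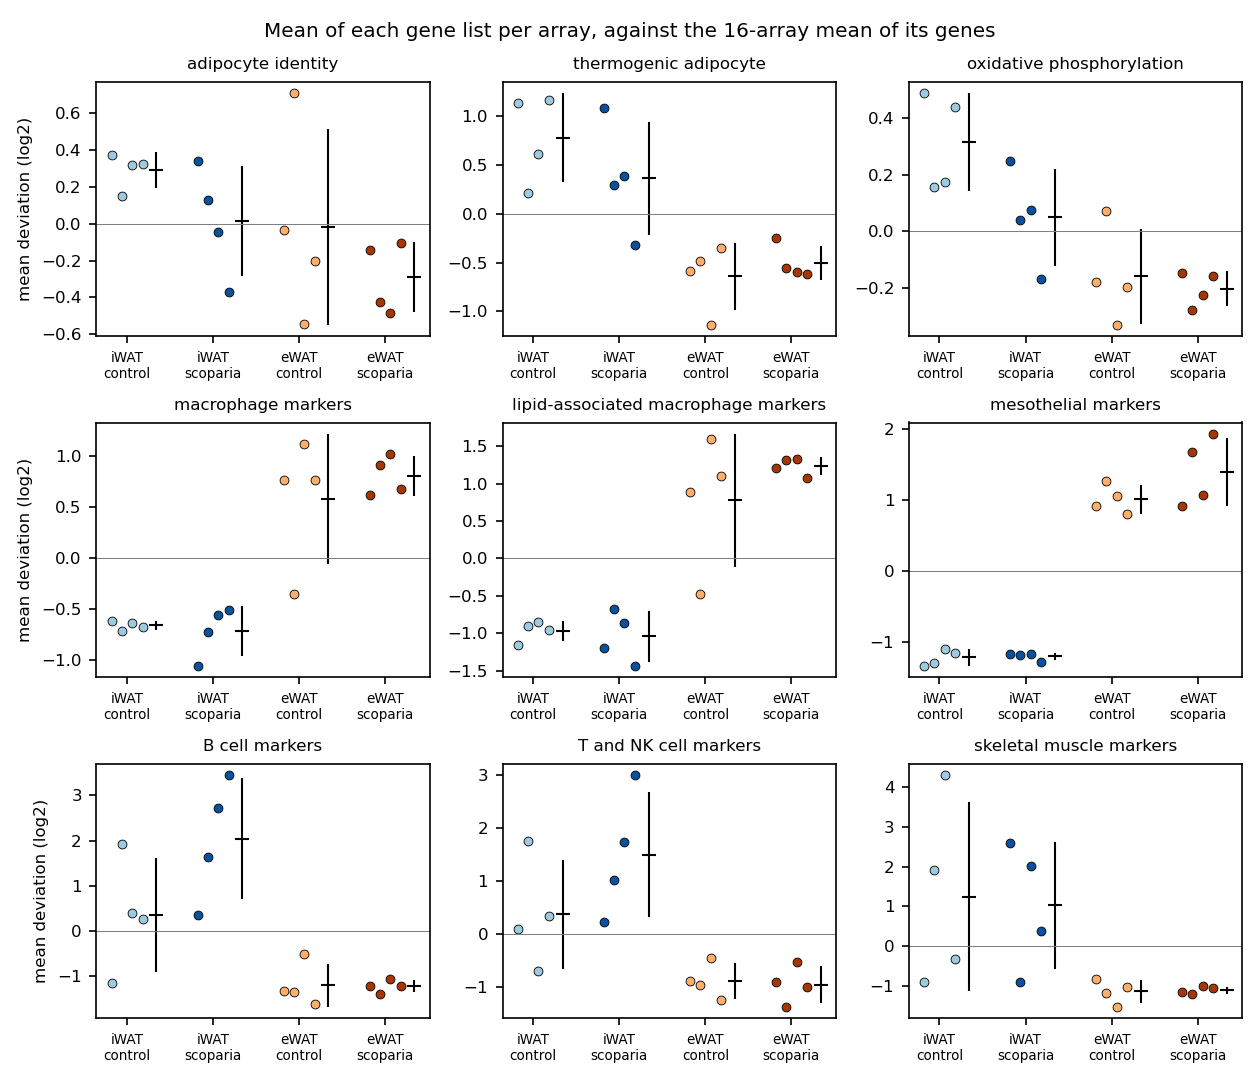
Mean deviation (log2) of the measured members of 9 gene lists from their mean over all 16 arrays, 1 point per array, with the mean ± SD of each group of 4 arrays. B cell markers, for example, have a mean of 0.36 ± 1.26 in iWAT control and 2.05 ± 1.34 in iWAT scoparia arrays.

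Of the adipose genes of interest, Slc2a4 (1.33 ± 0.41, adjusted p = 0.0292), Plin1 (1.13 ± 0.38, adjusted p = 0.0414) and Pnpla2 (0.66 ± 0.23, adjusted p = 0.0471) were higher in iWAT of control mice. Higher in eWAT were Ccl2 (-1.81, adjusted p = 0.0147), Lcn2 (-1.89, adjusted p = 0.0135), Adgre1 (-1.64, adjusted p = 0.00574), Cd68 (adjusted p = 0.000493), Itgax (-2.35, adjusted p = 0.000221) and Trem2 (-2.71, adjusted p = 0.00341). Over 29 settings Slc2a4 stayed called in 21, Plin1 in 17 and Pnpla2 in 13. The genes higher in eWAT stayed called in 27 to 29. The other 19 did not pass and lay between -1.76 for Saa3 (adjusted p = 0.052) and 1.47 for Pck1 (adjusted p = 0.0504). Under median scaling Scd1 turned from -0.09 to 0.82 (adjusted p = 0.0483), and leptin, Acly and Irs1 changed sign without passing. With the animal as a block, fitted on the 8 arrays of control mice alone, 405 genes passed (166 higher and 239 lower, 398 among the 2743). Median scaling gave 3989 genes (2989 higher, 1000 lower, with the median of all genes at 0.259 instead of 0.0761). The count was 1742 and 1500 without iWAT control arrays 1 and 4, 1562, 1775 and 1683 without eWAT control arrays 1, 3 and 4, and 1189 without both iWAT control arrays 1 and 4.

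In scoparia mice the depots differed at 1170 genes, 481 higher in iWAT and 689 higher in eWAT, 757 of them at least 2-fold. Of the genes called in each diet, 611 were called in both, and 608 of these had the same direction. Hoxc10 stood at 8.32 ± 0.68 in iWAT and was not detected in eWAT of scoparia mice, whereas Upk1b was not detected in iWAT. Across genes the depot effects of both diets correlated at r = 0.623. With the animal as a block, fitted on the 8 arrays of scoparia mice alone, 1887 genes passed (814 higher and 1073 lower, 1084 among the 1170). Array weights gave 3693. The count was 742 without iWAT scoparia array 3, and 687 and 710 without eWAT scoparia arrays 2 and 3.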

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

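Of the tests below, the splits of the iWAT genes and of the correlation between depots, the tests of all 3 explanations of the iWAT calls and all tests of the B and T cell markers were chosen only after the result was seen. For the held-out test and the test on the share of probes detected, the rule that turns a value into a verdict was also changed after its value was seen: the held-out test first counted against the explanation, and now leaves it open.

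Whether an arbitrary grouping calls as many genes was asked by exchanging labels in all 35 ways of dividing 8 arrays or 8 mice into 4 and 4. For the diet in iWAT 2 of 35 splits, the real one included, called at least the real 972 genes (highest other 1023), so that the count could have arisen from differences between the arrays other than diet. For eWAT and for both depots the real count is 0, which all 35 splits reach by definition (highest other 1 and 135), so that these 2 counts test nothing. For the difference between depots 2 of 35 reached 6 (highest other 81). For depot in control mice 2 of 35 reached 2743 (highest other 2960, which exchanged iWAT control array 3 with eWAT control array 2), and for depot in scoparia mice only the real split reached 1170 (highest other 0). Among the 8 splits that part both arrays of every animal, 1 reached 2743 (highest other 817) and 1 reached 1170 (highest other 0), but 8 splits are too few for a share under 0.05. For the lists 31 of 35 splits reached the real 3 in iWAT (highest other 15), 29 the 6 in eWAT (18), 25 the 5 over both depots (22), 30 the 3 for the difference (23) and 12 the 14 for depot in control mice (19). For the correlation of the diet effects between depots 12 of 35 reached 0.191 (highest other 0.385). The 35 splits for depot ignore the pairing by mouse, and the one with 2960 genes parts the arrays of only 2 of the 4 mice. Of the 611 genes called for depot in both diets, 608 had the same direction.

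The 1st pattern weighed is the set of 972 iWAT genes, which could come from iWAT control arrays 1 and 4 alone. Genes picked on these arrays against 2 scoparia arrays had a median of 1.61 to 1.84, and on the arrays held out 0.14 to 0.239 over 6 ways, with 68.3% to 80.1% in the same direction. The lowest was 0.14. Genes were also picked by the size of the difference alone, with the 6 ways averaged. There iWAT control arrays 2 and 3 gave 0.271 beside at most 0.264 for 14 other pairs in their place, which leaves this open. Their mean correlations with the iWAT scoparia arrays (0.972 and 0.962) were above those with their own group (0.952 and 0.938). These correlations go with the explanation. An axis of the share of probes detected, shared by both depots, correlated at -0.201 in eWAT (one-sided permutation p = 0.656; within iWAT 0.679, p = 0.0347, adjusted 0.139) and is open. An axis of lymphoid content correlated at 0.677 (one-sided permutation p = 0.0747, adjusted 0.149) and is open too.

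The 2nd pattern is the rise in B and T cell markers in iWAT, which may reflect how much of the inguinal lymph node was taken with the fat. Lymph node stromal and follicular genes (6 of 8 measured) were set against the B cell marker mean across 8 iWAT arrays of both diets. They correlated at r = 0.986 (permutation p = 9.92e-05, adjusted 0.000397 over 4 relations), which fits. By rank rho was 0.929, and without the 2 farthest arrays r was 0.964. This correlation cannot tell a piece of lymph node from lymphoid cells within the fat. With the diet means removed, B cell markers correlated at 0.979 with lymph node genes (permutation p = 0.00694, adjusted 0.0278), at 0.83 with T and NK cell markers (p = 0.0295, adjusted 0.0394), at 0.84 with the share of probes detected (p = 0.0156, adjusted 0.0312) and at 0.156 with muscle markers (p = 0.724). By splits, 6 of 35 gave a difference of at least 1.69 in the B cell mean (highest other 2.47), so that an arbitrary grouping is not excluded. Glycam1 stood at 5.02, 10.51, 7.72 and 8.82 on the iWAT control arrays and 8.50, 10.27, 11.02 and 12.04 on the iWAT scoparia arrays, against 4.34 to 4.69 in eWAT; histology of the pieces would settle it.

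The 3rd pattern is the lower adipocyte lists and higher list of lipid-associated macrophages in eWAT, which could come from eWAT control array 2. Without that array the difference of the adipocyte identity score was -0.029, against -0.272 with it (exact p = 0.486 for 4 against 4), and that of lipid-associated macrophages 0.0394 against 0.457 (exact p = 0.429), and this stays open, because neither difference passed with the array in. More macrophages and fewer adipocytes in some eWAT pieces is the other explanation: within the groups the scores of adipocyte identity and of macrophage markers, a list that did not pass itself, correlated at -0.981 (one-sided permutation p = 0.00521; -0.955 without control array 2), which fits. Most of either difference went with control array 2. Both explanations can hold together, since an array can stand apart through the cells in its piece. Counts of cells in the same pieces would show whether their make-up differed.

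Values lying far from the other 3 of their group (ratio of the gap to the range past the 5% point for 4 values) numbered 22 of 541 gene values and 6 of 128 list scores, where chance gives about 5%. On eWAT control array 2 they were Hcar1 (0.895), Cfd (0.844), Retn (0.96), Agt (0.853), Ivd (0.899), Timp1 (0.871), Mcm6 (0.902), Tlr8 (0.844) and the proliferation list (0.95). On iWAT control arrays they were Itgam (0.923) on array 1, Tnf (0.868) on array 2, Upk1b (0.835), Lilr4b (0.965), Hpgds (0.859) and Msln (0.83) on array 3, and Tnfrsf11b (0.841) on array 4. On iWAT scoparia arrays they were Tst (0.892) and Itgax (0.919) on array 1, Snx21 (0.872) on array 2 and Ddx3y (0.862) on array 4.

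On the other eWAT arrays they were the adipokines list on control array 3 (0.87), Ctcfl on control array 4 (0.871), Ddx6 (0.86) and the lists of de novo lipogenesis (0.909), thermogenic genes (0.853) and progenitor markers (0.857) on scoparia array 1, and Pld2 (0.874) and the circadian clock list (0.883) on scoparia array 4. The diet effect differed between the depots, with values of opposite sign, for Mindy2 (2.23), Reep3 (2.07), Bbx (2.01), Larp4b (1.94), the gene with a predicted name (1.58) and Gsc (-1.9). With the animal as a replicate block, which the pairing by mouse calls for, 0 genes passed for this difference. Lists whose effect differed were those of genes higher in subcutaneous fat (0.0249), T and NK cell markers (0.0145) and B cell markers (0.00335), the last 2 with values near 0 in eWAT. With an estimated correlation all 3 lists had an adjusted p of 0.974, and 30 of 35 splits gave at least 3 lists. Each rests on 4 arrays per group.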

How the results depend on the processing

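Of the alternatives below, the fits without iWAT control arrays 1 and 4, without eWAT control array 2 and without other pairs of iWAT arrays, the covariates, and for the depot lists fry, the block and the arrays left out were chosen only after the result was seen.

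For the diet in iWAT (972 genes) the authors' normalized values gave 1048, no background correction 1148, an offset of 50 1152, no detection filter 736, the stricter filter 1117, all detected probes 1067 and trend with robust moderation 960, with 670 (no filter) to 947 (the authors' values) of the 972 genes among them. Median scaling gave 2960, array weights 2154 and an adjusted p of 0.10 2661. The 8 arrays of the depot alone gave 0. Without iWAT control arrays 1 and 4 there were 4, and without other pairs of iWAT arrays 0 to 4978 (median 3; 14 of 27 pairs at most 4). As covariates the B cell marker mean gave 2, the muscle marker mean 2542 and the share of probes detected 0. The B cell mean and the share were higher in iWAT scoparia mice, so these fits cannot part them from the diet. With 1 array left out in turn the count ran from 0 (iWAT control array 4) to 3050 (iWAT control array 3).

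For eWAT (0 genes) array weights gave 147 and all other settings 0, with 0 (iWAT control array 1) to 14 over single arrays left out. Over both depots (0 genes) array weights gave 2796 and all other settings 0, with 0 to 2101 over single mice left out (highest without control mouse 3). A replicate block on the number shared by mice of both diets, which do not share an animal, gave 0 genes in iWAT, 0 in eWAT and 0 over both depots, and 4, 0 and 6 lists.

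For the difference between depots (6 genes) the authors' values gave 5 and the stricter filter 5, no background correction 14, median scaling 529, an offset of 50 11, no filter 3, all probes 2, trend with robust moderation 2, array weights 626 and an adjusted p of 0.10 126. The replicate block on the animal gave 0, and the fit without iWAT control arrays 1 and 4 gave 1. Single arrays left out gave 1 to 428 (iWAT control array 3).

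For depot in control mice (2743 genes) the settings without a block gave 2417 to 3989 and an adjusted p of 0.10 gave 4063. The replicate block on the animal, fitted on the 8 arrays of control mice, gave 405. The fit without iWAT control arrays 1 and 4 gave 1189, and that without eWAT control array 2 gave 3471. Single arrays left out gave 1500 (iWAT control array 4) to 4076 (iWAT control array 3). For depot in scoparia mice (1170 genes) array weights gave 3693. The replicate block, fitted on the 8 arrays of scoparia mice, gave 1887. The other settings gave 929 to 1712, with 687 to 1465 over single arrays left out. The correlation of the diet effects (0.191) was 0.194 with the authors' values, 0.181 without the filter and 0.375 with the depot genes left out, and 0.0597 to 0.258 with arrays left out.

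For the lists (3 in iWAT, 6 in eWAT, 5 over both depots, 3 for the difference, 14 for depot in control mice) camera with an estimated correlation gave 0 in all 5. Fry in 1 direction gave 0 in the 4 diet contrasts. For depot it gave 14, of which 11 were among camera's 14, without muscle, B cell and proliferation genes. In either direction fry gave 7, 0, 1 and 0 for the diet contrasts and 29 for depot. The 7 in iWAT shared 0 with camera's 3. They were the interferon response, branched-chain amino acid catabolism, xenobiotic genes, the unfolded protein response, lipolysis, the circadian clock and de novo lipogenesis. The 1 over both depots, the interferon response, was not among camera's 5. The authors' values gave 3, 6, 5 and 3 for the diet. Without iWAT control arrays 1 and 4 there were 7 in iWAT (2 of the 3 kept), 8 for the difference (3 of 3 kept) and 16 for depot (13 of 14 kept). Without control mice 1 and 4 there were 6 over both depots, with only 2 of the 5 kept. The replicate block on the animal gave 3 for the difference and, on the 8 arrays of control mice, 18 for depot. With single arrays left out the counts ran from 0 to 5 in iWAT, 0 to 11 in eWAT, 0 to 8 over both depots, 0 to 5 for the difference and 10 to 17 for depot.

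Of 662 results for named genes 169 were called, and 166 stayed called with the authors' values, 157 without background correction, 157 with median scaling, 164 with an offset of 50, 143 without the filter, 162 with all probes, 164 with trend and robust moderation and 158 with array weights. Far fewer stayed called on the 8 arrays of the depot alone (0 of 38) and without iWAT control array 1 (105), 4 (101) or both (84). With the replicate block on the animal, 60 of 126 stayed called for depot, fitted on the 8 arrays of control mice. For the difference 0 of 5 did. In these block fits 405 and 0 genes passed. With the B cell marker mean and the share of probes detected as covariates, both higher in iWAT scoparia mice, 1 and 0 of 38 stayed called. Directions that turned with a call were those of Adipoq in iWAT (-0.82 with median scaling), Scd1 for depot in control mice (0.82 with median scaling), and cholesterol synthesis in iWAT (adjusted p = 0.0493 without iWAT control arrays 1 and 4, higher) and over both depots (0.0277 without control mice 1 and 4, higher). A sign that changed while neither value was called is counted here as moved, not as reversed, which is a matter of definition. There were 248 such changes among 18364 gene values (114 of 662 results; 134 of them outside the runs with arrays left out) and 193 among 3200 list values (67 of 160 results; 36 outside).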

Other observations

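Of the tests in this part, fry for the depot lists was chosen only after the result was seen. Some gene lists that did not pass as a whole between the depots of control mice held members going both ways. Fry in either direction passed for 29 of the 32 lists, so that its small p values do not set these lists apart. In the unfolded protein response, 5 of 17 genes were higher in iWAT and 5 higher in eWAT (camera adjusted p = 0.513; fry in either direction 6.19e-09). The amino acid response genes Trib3 (1.16), Chac1 (0.99) and Asns (0.94) were higher in iWAT, and the chaperone Hspa5 was 2-fold higher in eWAT. In the circadian clock, 5 of 14 genes were higher in iWAT, among them Tef (1.06) and Dbp (0.96), whereas Per3 was at least 1.9-fold higher in eWAT (camera adjusted p = 0.744; fry in either direction 9.49e-07). Of 14 immediate early genes 5 were higher in iWAT, with Ccn1 at 1.84 and Ier3 at 0.75 next to Fosb, and 2 higher in eWAT, with Klf6 at -1.36 (camera adjusted p = 0.0921; fry in either direction 1.85e-07).

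Insulin signalling also parted in control mice: Grb14, an inhibitor of the insulin receptor, was higher in iWAT (1.84), and the kinase subunit Pik3ca (-1.41) and the phosphatase Ptpn1 (-0.96) were higher in eWAT (camera adjusted p = 0.96; fry in either direction 1.85e-07). Among interferon response genes Usp18 (1.42), Irf7 (1.11) and Bst2 (0.74) were higher in iWAT and Ifit2 (-0.86) in eWAT (camera adjusted p = 0.561, fry in either direction 3.72e-05). Over 29 settings Usp18 stayed called in 29, Bst2 in 27, Irf7 in 14 and Ifit2 in 13. Among xenobiotic and antioxidant genes Cyp1b1 (-2.05), Srxn1 (-1.45) and Hmox1 (-1.27) were higher in eWAT and Gsta4 (1.75) in iWAT (camera adjusted p = 0.0549). Single genes of other lists that passed were Retn (1.54), Cfd (1.00) and Aacs (0.98) in iWAT, and Metrnl (-1.86), Agt (-1.64), Stard4 (-1.49), Dcn (-1.04) and the cytokine genes Il1rn (-2.35), Ccl3 (-1.83) and Ccl9 (-1.60) in eWAT. The visceral factor Tcf21 and the keratin Krt14 were at least 2.51-fold and 3.9-fold higher in eWAT.

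The B cell marker mean and the muscle marker mean ranged over 4.60 and 5.23 in iWAT and over 1.10 and 0.71 in eWAT. Muscle markers stood at -0.92, 1.90, 4.31 and -0.34 on the iWAT control arrays and at 2.61, -0.91, 2 and 0.39 on the iWAT scoparia arrays. The mice had 1 iWAT and 1 eWAT array each, and deviations of a mouse's arrays from their group means correlated between -0.207 and 0.315.

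Body weight, food intake, glucose, insulin and fat pad weights were not analysed here. The signal of genes below the detection filter, such as Ucp1 and Il6, was not used here. Probe sequences were not used here, so that transcripts of 1 gene were not told apart.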
